A study of Rattus norvegicus with 105 samples.

How the data were processed

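RNA from rat frontal cortex had been hybridised to 105 Affymetrix rat arrays, which the labels place in 3 experiments and 11 groups. The lesion experiment held 12 arrays from rats with a lesion of the ventral hippocampus and 10 from sham-operated rats. The tetrodotoxin (TTX) experiment held 11 arrays from rats given this sodium channel blocker in the ventral hippocampus and 9 sham arrays. The neuroleptic experiment held 9 vehicle arrays, 10, 9 and 8 arrays at low, medium and high clozapine, and 9 arrays at each of low, medium and high haloperidol. Dose levels were words in the labels, so no amounts are given. The labels do not state that each array came from a separate animal, so p-values measure the spread between these samples, part of which may be technical. Replicate numbers follow the order of the samples in the series and pair nothing. Before any averaging the arrays were compared with each other, and 0 pairs held identical values; the highest correlation between any 2 arrays, over log2 values, was 0.955.

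The deposited table gave 1 intensity per probe set and array, on a linear scale and without missing values, for 31099 probe sets. The software, background correction and summarisation that the authors used are not given in the sources used here. The values themselves showed that each array had been scaled: the mean after trimming 2% at each end lay between 2500.6 and 2500.8 on every array, while the medians ran from 775.1 to 962.3. The number of arrays limits the precision of every value below. The table gave no detection calls, so probe sets near background could not be marked as such, and 6.04% of the values lay below the floor described next.

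The following choices were made before the data were examined: the groups, the normalisation for linear values, the floor, the filter, the tests, the lists, the 20 a priori genes, the rule for naming genes and the first set of alternatives. Intensities were quantile-normalised within each experiment, raised to a floor of 32 and converted to log2. The 57 control probe sets were left out, which left 31042, and the 60% with the highest mean in an experiment were tested, 18625 probe sets in each. Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 mean per group and no covariate, and Benjamini-Hochberg adjustment over the probe sets tested. A probe set was called at an adjusted p under 0.05. The lesion and TTX experiments were fitted alone, the 7 neuroleptic groups shared 1 residual spread, and the difference between the lesion and TTX effects came from a joint fit of both experiments. There were 14 comparisons. Figures were drawn with matplotlib 3.10.9.

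Gene names came from the platform's annotation table, brought up to date through Entrez gene identifiers in a table of the GRCr8 assembly, which changed 0 symbols; no coordinates were used. Of the probe sets without controls, 20826 had 1 symbol, 436 had several and stayed unnamed, and 9780 had none, which gave 14217 distinct symbols. A gene was represented by its probe set with the highest mean, whatever its other probe sets showed; where they differed, this is stated. Of the 20 a priori genes, 19 were measured and 1 is not reported here. Named genes were, in each main comparison, the 10 largest rises and 10 largest falls past the threshold plus up to 4 members of each list past it. Where fewer than 10 genes passed, the 5 with the smallest p in each direction were added as values. In single dose levels up to 3 called genes in each direction were named, and from each list up to 2 members as values where none passed. The a priori genes could be named anywhere. Calls of probe sets that do not represent their gene, and the called gene Fdft1 at high haloperidol, fell outside this rule and were named after their values were seen.

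Altogether 26 gene lists covered activity-regulated genes, receptors, synaptic genes, markers of neuronal, glial, vascular, meningeal, blood and striatal cells and of cortical layers, and metabolic and housekeeping pathways. Lists with at least 5 tested genes, 25 of the 26, were tested with limma's camera at a preset correlation of 0.01 between genes, on 1 probe set per gene, adjusted over the 25 lists. Camera with an estimated correlation and fry were run beside it. A list score was the mean of its members' log2 values, each centred on its mean over the experiment. Scores of the immediate early gene list were compared with two-sided permutation tests, exact for TTX and for single dose levels against vehicle and with 1e+05 permutations otherwise, adjusted over 11 comparisons.

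On simulated log2 values with 50 probe sets changed at each of 4 sizes among 18625, limma recovered 28% at a log2 change of 0.25 and 82% at 0.5 in a design like the lesion comparison. The shares were 18% and 74% for the TTX comparison, and 26% and 90% for the haloperidol mean against vehicle. All sizes and 1 shifted list were put into the same simulation, with noise drawn independently for each probe set. In all, 168, 154 and 164 simulated probe sets were called, in that order. The adjusted threshold is harder to pass where few probe sets change, so these shares may overstate recovery there. The alternatives chosen beforehand were values as deposited, a floor of 8, no filter, a stricter filter at 40%, a single fit over all arrays, array weights, and the sample number in the titles or a ratio of 3' to 5' control probe sets as covariate. For the lists they were an estimated correlation and the average of all probe sets of a gene. The labels do not say what the sample numbers in the titles record. Runs, blocks and array order below rest on these numbers alone. Further alternatives and tests were chosen after seeing the data, because the first principal component followed the sample numbers. For the lists the covariates and array weights were also added then. The others were a spline of the numbers, blocks of consecutive numbers, runs of consecutive arrays of 1 group as a random block, leaving out 7 arrays of low mean correlation (3 of the lesion experiment and 4 with haloperidol), and leaving out each neuroleptic array in turn. The tests between dose levels of the immediate early gene score, pooled and within blocks, and the exchanges of whole runs for the lesion, TTX and single dose levels were also chosen after seeing the data.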

Results

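Transcript levels in rat frontal cortex were measured on arrays from 3 experiments. In the lesion experiment the ventral hippocampus, which projects to the frontal cortex, had been lesioned in the rats behind 12 arrays, and 10 arrays came from sham-operated rats. In the TTX experiment the same region had been disrupted with tetrodotoxin, which blocks voltage-gated sodium channels and so silences neurons, for 11 arrays, with 9 sham arrays. The neuroleptic experiment compared chronic vehicle, on 9 arrays, with clozapine and haloperidol, an atypical and a typical antipsychotic, on 27 arrays each at 3 dose levels. The median SE of a log2 difference was 0.085 for the lesion, 0.084 for TTX, 0.083 for either drug mean against vehicle and 0.059 for clozapine against haloperidol. The first principal component held 16.05% of the variance in the lesion, 21.77% in the TTX and 23.15% in the neuroleptic arrays. Blocks of consecutive sample numbers in the titles held 37.7% of that component in the lesion and 79.4% in the neuroleptic arrays, where the 7 groups held 8.56%. The TTX arrays were divided into 2 blocks where the component was seen to jump, so its share in them is not given. For this reason values within blocks are given beside some of the pooled values.

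The lesion comparison asked how transcript levels in frontal cortex differ after damage to the ventral hippocampus. Immediate early genes, which neurons switch on with activity, stood lower after the lesion. Of 17 measured members 13 were lower and 4 higher, with a mean log2 difference of -0.18 (camera, adjusted p = 0.00125), but adjusted p = 0.496 with an estimated correlation. The list score lay below the sham mean in 10 of 12 lesion arrays, at -0.083 ± 0.19 (SD, n = 12) against 0.099 ± 0.18 (SD, n = 10) in sham. The two-sided permutation p was 0.0322, and 0.0590 after adjustment, or 0.171 with whole runs of consecutive arrays exchanged. Egr1, a zinc finger transcription factor, was at 13.97 ± 0.27 (SD, n = 12) log2 units after the lesion and 14.42 ± 0.24 (SD, n = 10) in sham. The difference of -0.45 ± 0.11 (SE) was seen in 11 of 12 lesion arrays. Its adjusted p was 0.411 over all probe sets and 0.00575 adjusted over the list alone. It was the only one of 18 a priori genes past the threshold there and the only immediate early gene past it within its list. Egr2 differed by -0.77 ± 0.30 in 10 of 12 arrays and the nuclear receptor Nr4a3 by -0.51 ± 0.18 in 11 of 12, neither past the threshold. Fos (-0.30 ± 0.35) and the synaptic scaffold Arc (-0.13 ± 0.23) lay within their errors, and the neurotrophin Bdnf was at 0.13 ± 0.14. All 5 probe sets of the synaptic scaffold Homer1 were lower, from -0.030 ± 0.086 to -0.49 ± 0.19, and none passed. In the first and second set of 11 arrays by sample number the list differed by -0.22 and -0.15.

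Another 7 lists were past the threshold after the lesion with camera's preset correlation. All 7 were lost with an estimated correlation, at adjusted p = 0.496 for the proteasome list and 0.565 for the others. Markers of GABAergic interneurons were higher, 14 of 18 with a mean of 0.13 in 9 of 12 arrays (adjusted p = 0.00828; 0.565 with an estimated correlation). Npy, which encodes neuropeptide Y, differed by 0.41 ± 0.12 in 11 of 12 arrays and was the only member past the threshold adjusted over the list alone (adjusted p over all probe sets 0.508). Tac3, a tachykinin precursor, was at 0.35 ± 0.20, while the GABA-synthesising enzyme Gad1 (0.017 ± 0.050) and parvalbumin, Pvalb (0.11 ± 0.091), lay nearer 0. Oligodendrocyte and myelin markers were lower, 18 of 20 with a mean of -0.11 in 8 of 12 arrays (adjusted p = 0.00125; 0.565 with an estimated correlation). Mog was at -0.28 ± 0.15, Car2 at -0.22 ± 0.12 and Mbp at -0.035 ± 0.054. Endothelial and mural markers (13 of 19 lower, mean -0.078, 8 of 12 arrays, adjusted p = 0.0152) were led by the contractile proteins Acta2 (-0.35 ± 0.13) and Myl9 (-0.23 ± 0.13). Postsynaptic density genes (16 of 21 lower, mean -0.048, 10 of 12 arrays, adjusted p = 0.0159) included Begain at -0.30 ± 0.15 and, in the other direction, Dlg2 at 0.21 ± 0.093. Respiratory chain genes stood slightly higher (58 of 73, mean 0.046, 8 of 12 arrays, adjusted p = 0.000169). So did ribosomal protein genes (35 of 41, 0.034, 7 of 12 arrays, adjusted p = 0.00119) and proteasome subunits (28 of 36, 0.057, 11 of 12 arrays, adjusted p = 0.00119). Rpl39 was far from its list at -0.78 ± 0.20. Within the first and second set of arrays the differences were 0.21 and 0.050 for interneuron markers, -0.23 and 0.013 for myelin, -0.054 and -0.10 for endothelium. They were 0.0043 and -0.10 for postsynaptic genes, 0.025 and 0.068 for the respiratory chain, 0.014 and 0.055 for ribosomal and 0.019 and 0.095 for proteasome genes. Without the arrays of low mean correlation, lesion replicates 1 and 7 and sham replicate 9, the means were -0.0067 for endothelial, -0.023 for postsynaptic, 0.0046 for ribosomal and 0.039 for proteasome genes, none past the threshold. Array weights likewise ended the postsynaptic (-0.034) and endothelial (-0.021) calls, and the stricter filter the endothelial call (-0.056).

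No single probe set passed in the lesion comparison: limma called 0 of 18625, with 1450 (7.79%) at an unadjusted p under 0.05. The genes with the smallest p on the higher side were the glyoxalase Glo1 at 0.17 ± 0.035 in 12 of 12 arrays, the transcription factor partner Arnt at 0.42 ± 0.090 in 12 of 12, Amacr (0.27 ± 0.057), Nsun4 (0.25 ± 0.054) and Vrk1 (0.31 ± 0.069). On the lower side were the calcium-binding protein Necab2 at -0.32 ± 0.066 in 11 of 12 arrays, R3hdm1 (-0.20 ± 0.047), Glis2 (-0.33 ± 0.076) and E2f4 (-0.25 ± 0.062), besides Egr1. Their adjusted p ran from 0.386 to 0.434. Markers of other cell types that surgery or dissection could bring were given as values. The astrocyte gene Gfap was at 0.17 ± 0.12, the microglial protease Ctss at 0.23 ± 0.096, the meningeal and growth factor gene Igf2 at -0.55 ± 0.37 and the blood genes Hbb and Alas2 at 0.0028 ± 0.18 and -0.10 ± 0.16. The dopamine receptor Drd1 was at 0.45 ± 0.19 in 11 of 12 arrays and the opioid precursor Penk at 0.39 ± 0.11 in 10 of 12, Penk being the only striatal marker past the threshold adjusted over its list alone.

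The TTX comparison asked how the frontal cortex differed after transmission from the same region had been disrupted rather than lost with the tissue. Oligodendrocyte and myelin markers were lower, 19 of 21 with a mean log2 difference of -0.11 in 9 of 11 arrays (camera, adjusted p = 2.35e-05; adjusted p = 0.601 with an estimated correlation). In the 2 blocks of sample numbers they differed by -0.15 and -0.099. Enpp2, which makes lysophosphatidic acid, was at -0.27 ± 0.20, Mbp at -0.045 ± 0.052, and the lineage factor Olig2 ran the other way at 0.32 ± 0.19. Dopamine receptor and signalling genes were higher, 10 of 13 with a mean of 0.12 in 10 of 11 arrays (adjusted p = 0.0281; adjusted p = 0.354 with an estimated correlation; 0.19 and 0.086 within blocks). Their largest member was Gnal, the G protein subunit that couples dopamine receptors to adenylyl cyclase, at 11.31 ± 0.24 (SD, n = 11) with TTX against 10.79 ± 0.20 (SD, n = 9) in sham. It differed by 0.52 ± 0.098 in 11 of 11 arrays and had the smallest p of the comparison, at an adjusted p of 0.499. Within the list alone it was the only member past the threshold. Striatal neuron markers, which share Gnal with the dopamine list, differed by 0.11 and 0.098 within the same blocks. Immediate early genes were higher, 13 of 17 with a mean of 0.14 in 8 of 11 arrays (adjusted p = 0.0281; adjusted p = 0.578 with an estimated correlation; 0.072 and 0.19 within blocks). Arc was at 0.32 ± 0.20 in 7 of 11 arrays and Junb at 0.29 ± 0.13 in 8 of 11. Fos (0.23 ± 0.26), Egr1 (-0.075 ± 0.12) and Bdnf (-0.056 ± 0.15) lay within their errors and all 5 Homer1 probe sets were below 0. The list score was 0.063 ± 0.18 (SD, n = 11) with TTX and -0.077 ± 0.086 (SD, n = 9) in sham. The exact two-sided permutation p was 0.0505, and 0.0695 after adjustment. With whole runs exchanged it was 0.100, the smallest value that the 20 arrangements of 3 against 3 runs allow. That exchange could therefore not fall under 0.05.

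Other genes with small p in the TTX comparison were Zbtb42, a zinc finger repressor, at 0.42 ± 0.089 in 10 of 11 arrays, Faf1 (0.24 ± 0.054), Dnai1 (0.37 ± 0.096) and Atg12 (0.18 ± 0.047) on the higher side. On the lower side stood Lrrc1 (-0.52 ± 0.13), Khnyn (-0.49 ± 0.13), Tm9sf3 (-0.30 ± 0.080), Abcb9 (-0.21 ± 0.058) and Kdm3b (-0.19 ± 0.054). Their adjusted p ran from 0.691 to 0.999. Limma called 0 of 18625 probe sets, with 867 (4.66%) at an unadjusted p under 0.05. Of 19 a priori genes 0 passed adjusted over the list alone. The immediate early and dopamine calls both ended with all probe sets of a gene averaged (0.12 and 0.10), the stricter filter (0.089 and 0.079), the sample number (0.12 and 0.098) or its spline (0.092 and 0.078) as covariate. The dopamine call also ended with array weights (0.095).

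A direct test of the difference between the lesion effect and the TTX effect asked whether removing and silencing the ventral hippocampus differed in the cortex. Immediate early genes stood apart most, lower after the lesion and higher after TTX. The lesion effect minus the TTX effect averaged -0.32 over 17 members, negative for 14 (camera, adjusted p = 0.000140; adjusted p = 0.168 with an estimated correlation). Permuting the labels within each experiment gave p = 0.00313 for the difference of the list scores, 0.0161 after adjustment, and exchanging whole runs of consecutive arrays p = 0.0171. Egr2 differed by -1.03 ± 0.43, the clock gene Per1 by -0.64 ± 0.27, Egr1 by -0.38 ± 0.16, Fos by -0.53 ± 0.46 and Arc by -0.45 ± 0.32, none past the threshold by itself. Respiratory chain (0.035, adjusted p = 0.0139), ribosomal protein (0.034, adjusted p = 0.00722) and proteasome genes (0.056, adjusted p = 0.0194) had small positive differences. These held for 55 of 73, 34 of 41 and 24 of 36 members, each at adjusted p = 0.609 with an estimated correlation. Without the arrays of low mean correlation these were 0.022, 0.0035 and 0.038, none past the threshold. With the spline the respiratory difference was 0.0085 and the proteasome difference 0.021, and with values as deposited the ribosomal difference turned to -0.00062, none past the threshold. The single genes with the smallest p were Mapre1 (0.27 ± 0.063), Pdcd5 (0.24 ± 0.064), Scarb2 (0.67 ± 0.19), Tsen15 (0.31 ± 0.087) and Pin4 (0.80 ± 0.23) on the positive side. On the negative side they were Zbtb42 (-0.55 ± 0.13), Trmt44 (-0.66 ± 0.16), Hcn2 (-0.57 ± 0.15), Necab2 (-0.39 ± 0.099) and Taok2 (-0.41 ± 0.12), and all had an adjusted p from 0.622 to 0.703. Limma called 0 probe sets, with 1179 (6.33%) at an unadjusted p under 0.05, and the median SE of this difference was 0.12. Adjusted over the list alone, 0 of the 19 a priori genes passed.

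**Figure D1:**
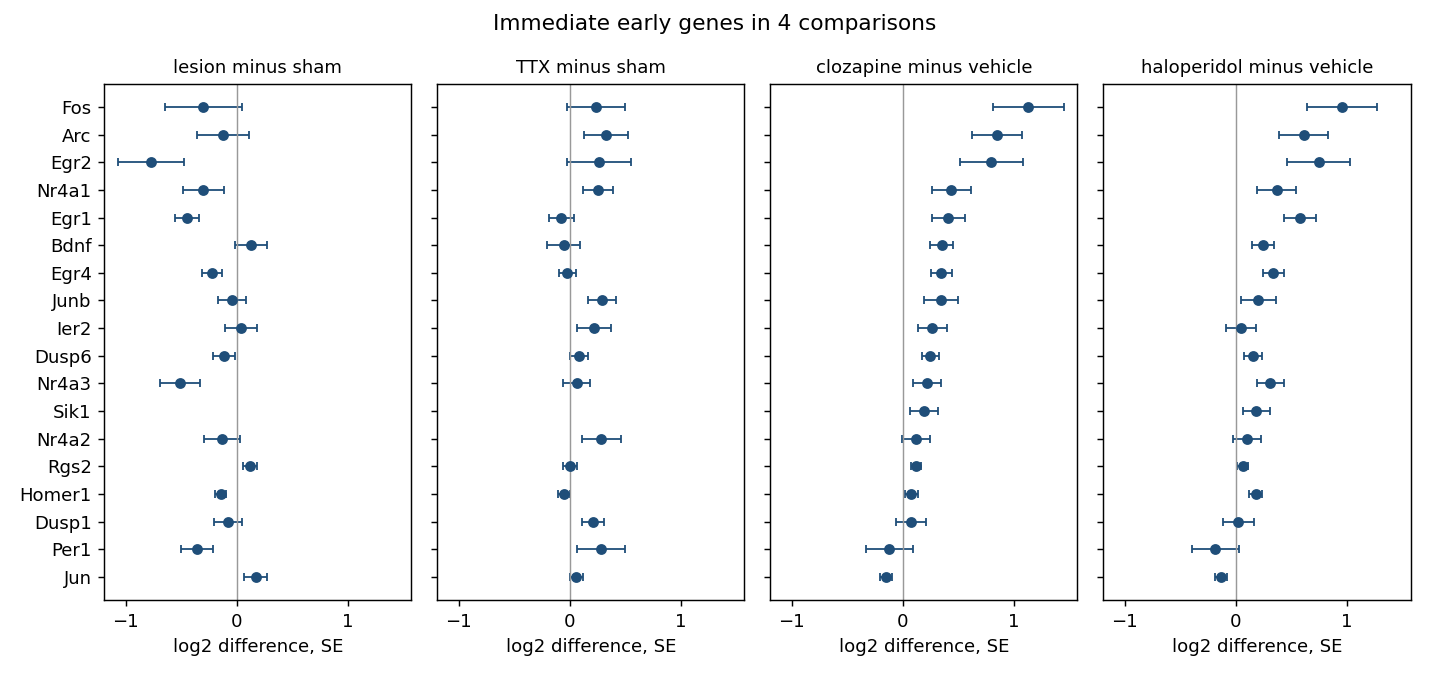
Log2 difference from control (points, with SE as bars) of each measured immediate early gene after the lesion, after TTX, with clozapine and with haloperidol, 1 panel each. 13 of 17 genes lie below 0 after the lesion and 13 of 17 above 0 after TTX, and 16 of 18 lie above 0 with either drug.

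The comparison of clozapine with vehicle asked what chronic treatment with this drug changed in frontal cortex. Immediate early genes rose with clozapine, 16 of 18 with a mean log2 difference of 0.32 over the 3 dose levels (camera, adjusted p = 8.42e-13), a call kept at 0.0121 with an estimated correlation and at 0.0210 with fry. The list score lay above the vehicle mean in 24 of 27 clozapine arrays, at 0.069 ± 0.28 (SD, n = 27) against -0.25 ± 0.26 (SD, n = 9). The two-sided permutation p was 0.00439 and 0.0161 after adjustment. Within blocks of sample numbers that held both, clozapine minus vehicle was 0.32, 0.43 and 0.22. Fos was at 11.09 ± 0.95 (SD, n = 27) with clozapine and 9.95 ± 1.15 (SD, n = 9) with vehicle, a difference of 1.13 ± 0.32 in 23 of 27 arrays. Arc was at 11.75 ± 0.77 (SD, n = 27) and 10.91 ± 0.46 (SD, n = 9), a difference of 0.84 ± 0.22 in 23 of 27. Egr1 (0.41 ± 0.14, 24 of 27 arrays) and Bdnf (0.35 ± 0.10, 25 of 27 arrays) were higher too. These 4 were past the threshold adjusted over the list alone of 19 a priori genes, at 0.0301 for Egr1 and 0.00632 for the others, but 0 were over all probe sets. Within the immediate early list alone 9 members were past on the higher side and 1 on the lower.

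With clozapine no probe set passed by itself, and Homer1 came nearest. A probe set that does not represent this gene differed from vehicle by 0.64 ± 0.12 in 26 of 27 arrays, at an adjusted p of 0.0559, while the representative probe set was at 0.078 ± 0.056. Limma called 0 of 18625 probe sets, with 711 (3.82%) at an unadjusted p under 0.05. Leaving out single arrays turned that probe set into a call in 12 of 63 cases, with the smallest adjusted p, 0.00699, without clozapine high replicate 7. The other arrays were vehicle replicates 2 (0.0287) and 8 (0.0287), clozapine medium 2 (0.0443) and 3 (0.0376), and clozapine low 3 (0.0270) and 5 (0.0457). They were also clozapine high 4 (0.0458) and 6 (0.0460), haloperidol low 2 (0.0224) and haloperidol high 3 (0.0493) and 8 (0.0444). The other genes with small p were Lsm11, a histone messenger processing factor, at 0.21 ± 0.048 in 25 of 27 arrays, Zmpste24 (0.22 ± 0.059), Slit1 (0.33 ± 0.091) and Ccn2 (0.30 ± 0.083) on the higher side. On the lower side they were Cln6 (-0.25 ± 0.075), Usp30 (-0.19 ± 0.060), Kat14 (-0.32 ± 0.10), Tnik (-0.15 ± 0.049) and Aass (-0.35 ± 0.11), and all had an adjusted p from 0.322 to 0.977. Heat shock and unfolded protein genes (18 of 21 higher, mean 0.035, 23 of 27 arrays, adjusted p = 0.0101, or adjusted p = 0.292 with an estimated correlation) held the chaperone Hsp90b1 at 0.13 ± 0.065 and, the other way, Dnajb9 at -0.21 ± 0.10. Ribosomal protein genes (30 of 41 higher, mean 0.027, 20 of 27 arrays, adjusted p = 0.00479, or adjusted p = 0.773 with an estimated correlation) were at 0.0053 with blocks as a term. Both calls ended with array weights (0.034 and 0.023).

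The comparison of haloperidol with vehicle asked the same of the typical drug. Homer1 rose by 0.73 ± 0.12 on 1 of its 5 probe sets, from 12.37 ± 0.26 (SD, n = 9) to 13.09 ± 0.35 (SD, n = 27), in 26 of 27 arrays (limma, adjusted p = 0.00434). The representative probe set was at 0.18 ± 0.056 (adjusted p = 0.508). Etv5, a transcription factor of the Ets family, rose by 0.39 ± 0.077, from 11.09 ± 0.20 (SD, n = 9) to 11.48 ± 0.20 (SD, n = 27), in 26 of 27 arrays (adjusted p = 0.0246). The membrane transporter Mfsd4a fell, with a difference of -0.19 ± 0.038, at 13.30 ± 0.10 (SD, n = 27) against 13.50 ± 0.084 (SD, n = 9), in 27 of 27 arrays (adjusted p = 0.0246). Fdft1, the squalene synthase of sterol synthesis, fell with a difference of -0.19 ± 0.040, at 12.84 ± 0.099 (SD, n = 27) against 13.04 ± 0.092 (SD, n = 9), in 26 of 27 (adjusted p = 0.0498). These were the 4 calls among 18625 probe sets, 2 higher and 2 lower, with 1261 (6.77%) at an unadjusted p under 0.05. Immediate early genes rose, 16 of 18 with a mean of 0.27 in 24 of 27 arrays (camera, adjusted p = 5.48e-12; adjusted p = 0.0176 with an estimated correlation; fry 0.104). Their score was 0.014 ± 0.25 (SD, n = 27) against -0.25 ± 0.26 (SD, n = 9) with vehicle, a two-sided permutation p of 0.010 and 0.0220 after adjustment. Within blocks haloperidol minus vehicle was 0.46 for 7 arrays, 0.20 for 1 and -0.047 for 2. Fos was at 0.95 ± 0.32 (23 of 27 arrays), Egr2 at 0.74 ± 0.28 (22 of 27), Arc at 0.61 ± 0.22 (25 of 27), Egr1 at 0.58 ± 0.14 (24 of 27) and Bdnf at 0.24 ± 0.10 (23 of 27). Within the immediate early list alone 8 members were past the threshold on the higher side and 1 on the lower. Of the 19 a priori genes 0 passed over all probe sets and 4 passed adjusted over the list alone, Egr1 (0.00338), Homer1 (0.0221), Fos (0.0238) and Arc (0.0410).

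Of the 4 haloperidol calls, 3 depended on single arrays and all 4 on how the order of the sample numbers was modelled. Homer1 passed in 63 of 63 cases with 1 array left out, at an adjusted p of at most 0.0369. With the adjusted p in brackets, Etv5 ended without vehicle replicate 1 (0.146), 2 (0.0642), 3 (0.0925), 5 (0.0715), 6 (0.105) or 7 (0.163) and Mfsd4a without vehicle replicate 1 (0.228), 2 (0.0840), 3 (0.0755), 4 (0.0610), 6 (0.105) or 7 (0.0753). Fdft1 ended in 47 of 63 cases, at most 0.418 without vehicle replicate 1. The count of calls was 1 without vehicle replicate 1, 2, 3, 6 or 7 and 2 without vehicle replicate 4 or 5. With blocks as a term all 4 ended, Homer1 at 0.71 ± 0.15 (adjusted p = 0.419), Etv5 at 0.34 ± 0.087, Mfsd4a at -0.17 ± 0.044 and Fdft1 at -0.16 ± 0.045. With runs of arrays as a random block Homer1 kept its size at 0.74 ± 0.15 with a larger error (adjusted p = 0.223). The 3'/5' log2 ratio, a reading of RNA integrity, was 0.50 ± 0.061 (SD, n = 9) with vehicle and 0.57 ± 0.072 (SD, n = 27) with haloperidol. With this ratio as covariate Etv5 at 0.36 ± 0.081 (adjusted p = 0.221), Mfsd4a at -0.18 ± 0.040 (0.221) and Fdft1 at -0.16 ± 0.041 (0.391) were not past the threshold, and Homer1 was (0.0330). Fdft1 also ended without the arrays of low mean correlation (0.125). Another 5 lists were past the threshold with small means and were lost with an estimated correlation, at adjusted p = 0.255 for the postsynaptic, 0.612 for the respiratory and 0.218 for the other 3 lists. Postsynaptic density genes were at 0.059 (14 of 21 higher, 19 of 27 arrays, adjusted p = 0.00432), with Dlg4 at 0.29 ± 0.11 and Dlg2 at 0.26 ± 0.092. Glutamate receptors were at 0.063 (13 of 19, 21 of 27 arrays, adjusted p = 0.0350), with Grm5 at 0.44 ± 0.17 and Grin3a at 0.36 ± 0.14. Deep layer markers were at 0.058 (10 of 14, 20 of 27 arrays, adjusted p = 0.0250), with Bcl11b at 0.24 ± 0.097. Growth factors were at 0.052 (8 of 15, 19 of 27 arrays, adjusted p = 0.0252), with Igf1r at 0.22 ± 0.095. Respiratory chain genes were lower at -0.032 (56 of 73, 21 of 27 arrays, adjusted p = 0.0350), with Uqcrc1 at -0.12 ± 0.054. With the spline of sample numbers the postsynaptic mean was 0.0039 and the glutamate receptor mean 0.013, and with the 3'/5' ratio as covariate the respiratory mean was -0.0094. With blocks as a term the postsynaptic mean was 0.031, the glutamate receptor mean 0.022 and the growth factor mean 0.023. The growth factor mean was 0.014 without the filter and the deep layer mean 0.052 with the spline, and none of these passed. Further genes with small p were Eif4e3 at 0.40 ± 0.093, Grb14 (0.26 ± 0.061) and Zmpste24 (0.24 ± 0.059) on the higher side and Epb41 (-0.30 ± 0.077), Crhbp (-0.28 ± 0.072) and Bckdk (-0.21 ± 0.055) on the lower.

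The dose levels of clozapine were compared with vehicle to see at which level the immediate early genes stood highest. At the medium level Fos rose by 2.02 ± 0.39, from 9.95 ± 1.15 (SD, n = 9) to 11.97 ± 0.49 (SD, n = 9), in 9 of 9 arrays (limma, adjusted p = 0.0113). Arc rose by 1.46 ± 0.27, from 10.91 ± 0.46 (SD, n = 9) to 12.37 ± 0.81 (SD, n = 9), in 8 of 9 (adjusted p = 0.00993). Homer1 rose on 2 of its 5 probe sets, by 0.83 ± 0.15 and 1.16 ± 0.21, each in 9 of 9 arrays (adjusted p = 0.00993 for both). As a list, 17 of 18 immediate early genes were higher at the medium level, with a mean of 0.57 in 9 of 9 arrays (camera, adjusted p = 1.64e-23; 0.000128 with an estimated correlation; fry 0.000112). Of these, 12 passed within the list alone. The mean was 0.25 at the low level (8 of 10 arrays, adjusted p = 1.08e-07; adjusted p = 0.145 with an estimated correlation) and 0.13 at the high level (7 of 8 arrays, adjusted p = 0.0643). The score was 0.00016 ± 0.25 (SD, n = 10) at low, 0.31 ± 0.19 (SD, n = 9) at medium and -0.12 ± 0.18 (SD, n = 8) at high clozapine. The exact permutation p against vehicle was 0.0487, 0.000370 and 0.245, or 0.0695, 0.00407 and 0.245 after adjustment. Medium exceeded low by 0.31 (exact permutation p = 0.00914, adjusted over 6 tests 0.0274). It exceeded high by 0.44 (exact permutation p = 0.000411, adjusted 0.00247). High and low differed by -0.12 (exact permutation p = 0.271). The difference between medium and high was 0.22, 0.52, 0.56 and 0.48 in the 4 blocks that held both. Exchanging labels within blocks gave an exact p of 0.00139. The difference between medium and low was -0.053, 0.73 and 0.38 in the 3 blocks that held both, where the same exchange gave an exact p of 0.0444. These tests exchanged single arrays. Exchanging whole runs of consecutive arrays gave an exact p of 0.0286 for medium against high and 0.0714 for medium against low. Against vehicle it was 0.119 for low, 0.0286 for medium and 0.229 for high clozapine. With 4 against 4 runs 0.0286 is the smallest value that the 70 arrangements allow.

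At high clozapine the call was Ccn2, a matricellular growth factor used here as a deep layer marker, which rose by 0.60 ± 0.10, from 11.79 ± 0.14 (SD, n = 9) to 12.39 ± 0.19 (SD, n = 8), in 8 of 8 arrays (limma, adjusted p = 0.00553). At low clozapine limma called 0 probe sets, with 507 at an unadjusted p under 0.05. The unadjusted counts were 755 at medium, with 4 calls, and 723 at high, with 1. A priori genes past the threshold adjusted over the list alone numbered 0 at low, 4 at medium (Egr1, Bdnf, Arc and Fos) and 0 at high clozapine. Ribosomal protein genes were past the threshold in 3 comparisons of levels, each lost with an estimated correlation. They were slightly higher at medium (0.035, 33 of 41, 8 of 9 arrays, adjusted p = 0.00492) and high clozapine (0.048, 36 of 41, 6 of 8 arrays, adjusted p = 2.05e-05). They were higher at the high than at the low level by 0.050 (39 of 41, 6 of 8 high arrays, adjusted p = 3.63e-06). With an estimated correlation these were at adjusted p = 0.780, 0.564 and 0.578. Another 5 list calls at low and medium clozapine were lost in the same way. Heat shock genes were higher at low (0.042, adjusted p = 0.0165) and medium (0.040, adjusted p = 0.0250), presynaptic vesicle genes at low (0.049, adjusted p = 0.0269) and respiratory chain genes at medium clozapine (0.032, adjusted p = 0.0246). Microglial markers were lower at low clozapine (-0.091, adjusted p = 0.0181). In that order their adjusted p was 0.204, 0.535, 0.427, 0.801 and 0.395 with an estimated correlation. Presynaptic genes at low clozapine were at 0.021 with the spline, microglial markers at -0.040 with the stricter filter, and at medium respiratory chain genes at 0.016 and ribosomal genes at 0.020 with blocks, none past the threshold. High against low clozapine gave 0 calls with limma, 602 probe sets at an unadjusted p under 0.05 and 0 a priori genes adjusted over the list alone. Without vehicle replicate 1 or 5 Fos at the medium level ended at adjusted p = 0.0529 and 0.0596. With runs of arrays as a random block all 5 calls were lost at nearly the same size, Fos at 2.06 ± 0.51 (adjusted p = 0.639), Arc at 1.49 ± 0.35 (0.572) and Ccn2 at 0.60 ± 0.13 (0.708). With blocks as a term Fos (adjusted p = 0.0134), Arc (0.0134) and Ccn2 (0.0140) passed.

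**Figure D2:**
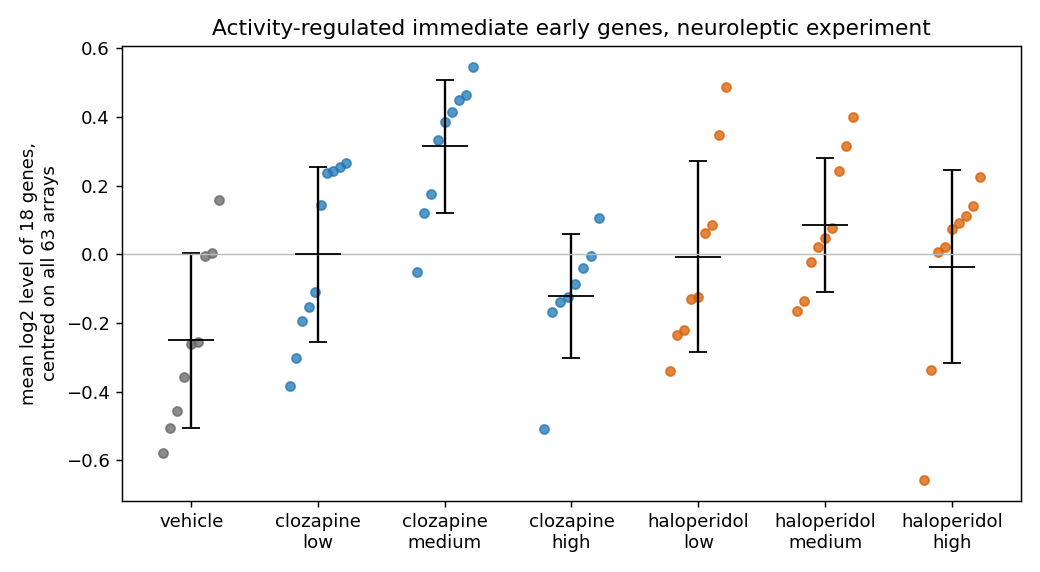
Immediate early gene score per array (points, mean of centred log2 values over 18 genes) with group mean and SD for vehicle and 3 dose levels of clozapine and haloperidol. The medium clozapine group has the highest mean, 0.31, and vehicle the lowest, -0.25.

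**Figure D3:**
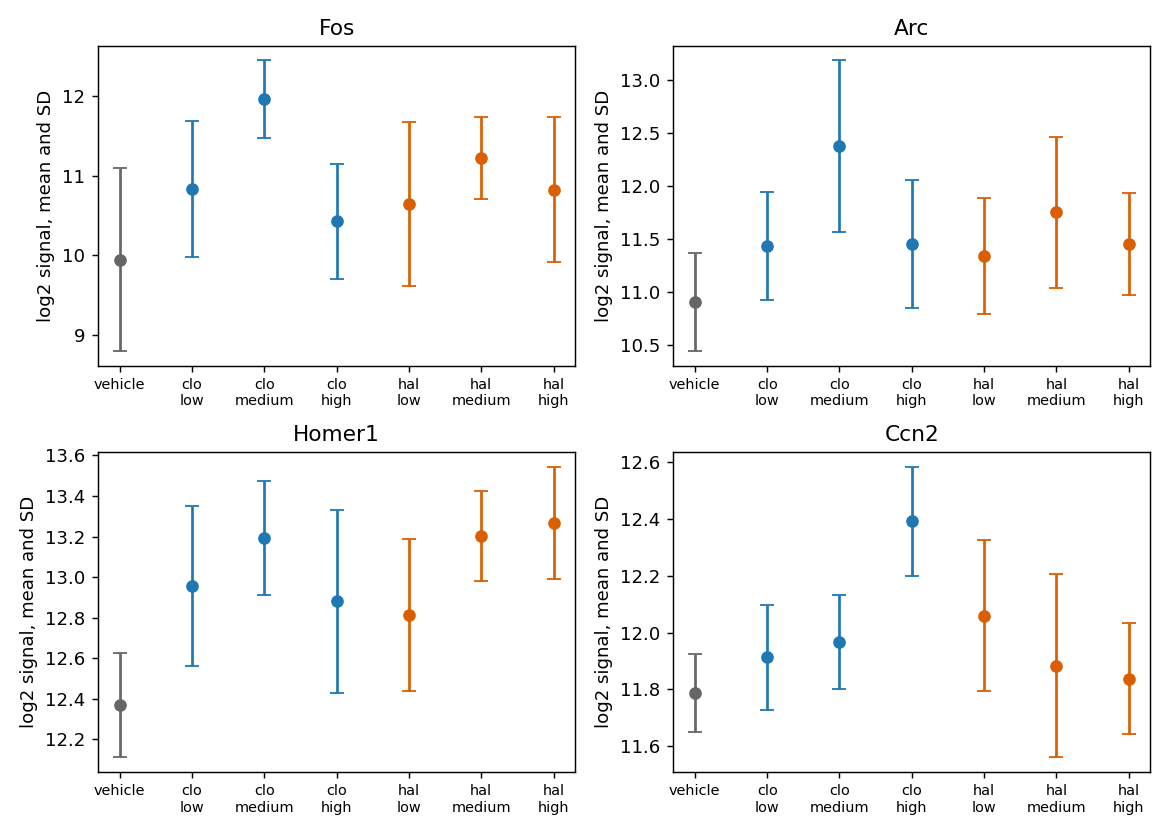
Mean log2 signal with SD of Fos, Arc, Homer1 and Ccn2 in the 7 neuroleptic groups. Fos and Arc are highest at medium clozapine and Ccn2 at high clozapine, where its mean is 12.39 against 11.79 with vehicle.

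The dose levels of haloperidol showed the same Homer1 probe set at the medium and high levels. Homer1 rose by 0.83 ± 0.15 at medium, from 12.37 ± 0.26 (SD, n = 9) to 13.20 ± 0.22 (SD, n = 9), in 9 of 9 arrays (limma, adjusted p = 0.0172). It rose by 0.90 ± 0.15 at high haloperidol, to 13.27 ± 0.28 (SD, n = 9), in 9 of 9 (adjusted p = 0.00169). At the low level it was at 0.44 ± 0.15 (adjusted p = 0.999). At the high level 4 genes fell, each in 9 of 9 arrays. Mfsd4a was at -0.28 ± 0.047 (adjusted p = 0.00169) and Fdft1 at -0.27 ± 0.049 (adjusted p = 0.00561). Bckdk, the kinase that restrains branched-chain amino acid breakdown, was at -0.34 ± 0.068 (adjusted p = 0.0263), and Epb41, a membrane skeleton protein, at -0.45 ± 0.094 (adjusted p = 0.0349). Immediate early genes averaged 0.24 at low (8 of 9 arrays, adjusted p = 3.08e-08; adjusted p = 0.0920 with an estimated correlation). They averaged 0.34 at medium (9 of 9 arrays, adjusted p = 2.91e-12; adjusted p = 0.0155 with an estimated correlation) and 0.21 at high haloperidol (7 of 9 arrays, adjusted p = 6.75e-06; adjusted p = 0.186 with an estimated correlation). The score was -0.0073 ± 0.28 (SD, n = 9) at low, 0.086 ± 0.20 (SD, n = 9) at medium and -0.036 ± 0.28 (SD, n = 9) at high. The exact permutation p against vehicle was 0.0710, 0.00740 and 0.108, or 0.0868, 0.0204 and 0.119 after adjustment. Exchanging whole runs it was 0.143, 0.0286 and 0.143, where 0.0286 is the smallest value that 4 against 4 runs allow. Between levels the score differed by 0.094 (medium minus low), 0.12 (medium minus high) and -0.029 (high minus low). The exact permutation p was 0.416, 0.315 and 0.831. Egr1 at low haloperidol (0.60 ± 0.18, 8 of 9 arrays) was the 1 a priori gene past the threshold there adjusted over the list alone. At medium these were Egr1, Homer1, Arc and Fos, and at high 0.

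GABAergic interneuron markers were lower at high haloperidol, 15 of 18 with a mean of -0.095 in 9 of 9 arrays (camera, adjusted p = 0.00489; adjusted p = 0.160 with an estimated correlation; fry 0.0101). They differed by -0.084 from the low level (adjusted p = 0.0160; adjusted p = 0.258 with an estimated correlation). The peptide binding protein Crhbp was at -0.37 ± 0.088 and Npy at -0.26 ± 0.060 against vehicle, with reelin, Reln, at -0.21 ± 0.13, Gad1 at -0.071 ± 0.061 and Pvalb at -0.059 ± 0.065. Sterol and fatty acid synthesis genes were lower at the high level, 20 of 26 with a mean of -0.075 in 7 of 9 arrays (adjusted p = 0.00616; adjusted p = 0.279 with an estimated correlation; fry 0.0309), Fdft1 being the member past the threshold. Growth factors were higher at medium haloperidol (0.091, 12 of 15, 8 of 9 arrays, adjusted p = 0.00160, kept at 0.0310 with an estimated correlation; fry 0.246) but not past the threshold with the spline (0.083) or blocks (0.054). At low haloperidol 6 lists were past the threshold that were lost with an estimated correlation. Glutamate receptors (0.11, 9 of 9 arrays, adjusted p = 0.00329), deep layer markers (0.084, 0.00329), presynaptic (0.053, 0.00697) and postsynaptic genes (0.052, 0.0124) were higher. Microglial markers (-0.11, 0.00452) and respiratory chain genes (-0.041, 0.00321) were lower. In that order these were at adjusted p = 0.0920, 0.110, 0.516, 0.516, 0.299 and 0.714 with an estimated correlation. With the spline the presynaptic mean turned to -0.020 and the postsynaptic to -0.031, and the glutamate receptor mean was 0.029. With blocks these 3 were at 0.00026, 0.0079 and 0.052, and the respiratory mean was -0.023 with the 3'/5' ratio, none past the threshold. Postsynaptic genes were also at 0.063 at medium (adjusted p = 0.0162, or adjusted p = 0.376 with an estimated correlation) and 0.063 at high (adjusted p = 0.0154, or adjusted p = 0.436 with an estimated correlation). With the spline these were 0.0018 and 0.040, not past the threshold. Ribosomal protein genes were higher at high haloperidol (0.037, adjusted p = 0.000216, or adjusted p = 0.465 with an estimated correlation) and exceeded the low level by 0.059 (adjusted p = 4.10e-06, or adjusted p = 0.566 with an estimated correlation). Limma called 0 probe sets at low haloperidol (792 at an unadjusted p under 0.05), 1 at medium (874), 5 at high (1442) and 0 for high against low (1029), where 0 a priori genes passed adjusted over the list alone.

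Single arrays and the order of the sample numbers limited the haloperidol dose calls. With the adjusted p in brackets, Homer1 at medium ended without haloperidol medium replicate 1 (0.0719), 6 (0.0671) or 7 (0.0828) or vehicle replicate 3 (0.0823), 5 (0.0655), 6 (0.0515) or 9 (0.0566). Bckdk ended without vehicle replicate 1 (0.112), 2 (0.0540), 4 (0.0520) or 6 (0.0815) or haloperidol high replicate 2 (0.0571), 7 (0.111) or 9 (0.0824), and Epb41 without vehicle replicate 1 (0.115), 2 (0.0540), 3 (0.0536), 4 (0.0626), 6 (0.0852) or 7 (0.130) or haloperidol high replicate 5 (0.0676), 7 (0.210), 8 (0.111) or 9 (0.0515). With blocks as a term Homer1 and Mfsd4a at high haloperidol passed (adjusted p = 0.0188 for both) and Homer1 at medium did not (adjusted p = 0.724), nor did Fdft1 (0.0636), Bckdk (0.0693) and Epb41 (0.135) at high. With the spline Homer1 at high passed (0.0127), but Mfsd4a at -0.20 ± 0.049 (0.216), Fdft1 (0.264), Bckdk (0.233) and Epb41 (0.500) did not, nor Homer1 at medium (0.241). With runs as a random block Homer1 at high was at 0.91 ± 0.19 (adjusted p = 0.0989) and Mfsd4a at -0.28 ± 0.059 (0.0989). The 3'/5' log2 ratio was 0.60 ± 0.055 (SD, n = 9) at high haloperidol against 0.50 ± 0.061 (SD, n = 9) with vehicle. With it as covariate Fdft1 at high was at -0.23 ± 0.051 (0.209), Bckdk at -0.27 ± 0.070 (0.493) and Epb41 at -0.44 ± 0.10 (0.249). The mean of the interneuron markers at high haloperidol was -0.048 with that covariate and -0.058 without the arrays of low mean correlation, haloperidol high replicates 7 and 8 among them. The ribosomal mean was -0.0085 without them, and none of these passed. For high against low haloperidol the interneuron mean was -0.051 without those arrays and -0.065 with array weights. The ribosomal mean was 0.012 and 0.032, none past the threshold. Bckdk (adjusted p = 0.237) and Epb41 (0.343) at high also ended without them.

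A direct comparison of the drugs asked which genes differ between clozapine and haloperidol, means of 3 dose levels each. Limma called 225 of 18625 probe sets, 62 higher and 163 lower with clozapine, with 2823 (15.2%) at an unadjusted p under 0.05. Of the genes with a name 31 were higher and 48 lower. The largest differences on the higher side were the acetyltransferase subunit Naa25 at 0.45 ± 0.11 in 24 of 27 clozapine arrays, then Nutf2 (0.35 ± 0.092), Mas1 (0.32 ± 0.080), Pias1 (0.32 ± 0.069), Emsy (0.29 ± 0.055), Prcc (0.27 ± 0.072), Slu7 (0.26 ± 0.063), Hdgf (0.26 ± 0.071), Lrrc20 (0.26 ± 0.071) and Hecw1 (0.26 ± 0.068). Naa25 was at 10.15 ± 0.40 (SD, n = 27) for clozapine, 9.70 ± 0.35 (SD, n = 27) for haloperidol and 10.06 ± 0.62 (SD, n = 9) for vehicle. On the lower side they were Tsc22d2 at -0.57 ± 0.13 in 23 of 27 arrays, the vesicle traffic GTPase Rab14 at -0.55 ± 0.14, Zbtb41 (-0.51 ± 0.12), Cdh22 (-0.50 ± 0.12), Nhsl2 (-0.45 ± 0.11) and Pgpep1 (-0.43 ± 0.11), the splicing regulator Rbfox2 at -0.42 ± 0.090, Zfp451 (-0.41 ± 0.11), Ggact (-0.41 ± 0.079) and Dnajb14 (-0.39 ± 0.11). Their adjusted p ran from 0.0157 to 0.0495. Npy was higher with clozapine by 0.15 ± 0.035 in 23 of 27 arrays (adjusted p = 0.0241). So were the GABA receptor subunit Gabrb1 by 0.24 ± 0.063 in 19 (adjusted p = 0.0397) and the glucocorticoid-responsive factor Klf9 by 0.085 ± 0.023 in 22 (adjusted p = 0.0447). Npy was at 13.74 with clozapine, 13.58 with haloperidol and 13.73 with vehicle. In the same order Gabrb1 was at 13.06, 12.82 and 12.99 and Klf9 at 14.10, 14.01 and 14.10. For Npy, Gabrb1 and Klf9 the vehicle mean lay nearer the clozapine mean than the haloperidol mean. Among the named genes with the largest differences it lay nearer the haloperidol mean for Mas1, Emsy, Slu7, Hdgf and Ggact. For the others of them it lay nearer the clozapine mean. GABAergic interneuron markers were higher with clozapine, 15 of 18 with a mean of 0.063 in 25 of 27 arrays (camera, adjusted p = 0.0379; adjusted p = 0.444 with an estimated correlation; fry 0.00335). Endothelial and mural markers (0.10, 14 of 19, 22 of 27 arrays, adjusted p = 0.0477), with Tagln at 0.58 ± 0.20 and Vwf at 0.30 ± 0.12, and respiratory chain genes (0.036, 59 of 73, 20 of 27 arrays, adjusted p = 0.0182) were higher too, both at adjusted p = 0.847 with an estimated correlation. Immediate early genes, higher with each drug against vehicle, differed by 0.050 between the drugs (adjusted p = 0.877), and 0 of 19 a priori genes passed adjusted over the list alone.

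The 225 calls ended under several other models. The count was 0 with limma when the 3'/5' ratio, the spline, blocks or runs entered the model, or when the 4 neuroleptic arrays of low mean correlation were left out. These were all haloperidol arrays, high replicates 7 and 8, low replicate 9 and medium replicate 9. The main model had 2823 probe sets at an unadjusted p under 0.05. The median difference of the 225 in their called direction was 0.32 with a median SE of 0.080, against 0.23 and 0.083 with the ratio. It was 0.10 and 0.11 with the spline, 0.28 and 0.080 without those arrays and 0.32 and 0.10 with runs as a random block. The 3'/5' log2 ratio of control probe sets was 0.51 ± 0.055 (SD, n = 27) with clozapine and 0.57 ± 0.072 (SD, n = 27) with haloperidol, a permutation p of 0.00135. In the 4 blocks that held more than 1 array of each drug the median difference of the 225 in their called direction was 0.43, 0.22, 0.32 and 0.080. A block with 6 clozapine arrays and 1 haloperidol array was left out. The interneuron mean was 0.034 with the ratio, 0.037 with the spline, 0.032 with blocks and 0.057 with array weights. The endothelial mean was 0.031 with blocks and the respiratory mean 0.015 with the ratio, none past the threshold. Leaving out 1 array moved the count by over 1.5 times in 30 of 63 cases. It became 73, 661, 142, 110, 89 and 149 without clozapine high replicates 1, 2, 3, 5, 6 and 8. It was 143, 116, 94, 97, 441 and 370 without clozapine low replicates 2, 6, 7, 8, 9 and 10, and also fell by over 1.5 times without replicate 3. It was 429, 143, 89, 137 and 147 without clozapine medium replicates 1, 2, 5, 6 and 8. It became 137, 56 and 130 without haloperidol high replicates 5, 7 and 9. It was 118, 124, 340, 113 and 96 without haloperidol low replicates 4, 6, 7, 8 and 9. It was 144, 128, 100 and 70 without haloperidol medium replicates 4, 5, 8 and 9.

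Fold changes were compared between experiments to ask whether the lesion or TTX resembled either drug across genes. Pearson correlations across probe sets, which are not independent replicates, were -0.041 between lesion and TTX, 0.10 and 0.014 between lesion and clozapine or haloperidol, and -0.076 and -0.11 between TTX and clozapine or haloperidol. Regrouped arrays gave a correlation at least as far from the mean of the regroupings in 54, 63, 85, 60 and 54 of 100 regroupings, in that order. Clozapine and haloperidol, which share the vehicle arrays, correlated at 0.49 with 67.5% of signs shared, below the mean of 0.74 ± 0.12 (SD) and 76.9% that 100 regroupings of the same arrays gave. Of these 100 regroupings, 4 gave a correlation at least as far from that mean. The covariance was 0.0055 against 0.0079 in the regroupings. With disjoint vehicle arrays, 5 for one drug and 4 for the other, the correlation was -0.032 ± 0.14 (SD over 100 divisions).

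Several lists passed in none of the 14 comparisons, with values given for the lesion. GABA receptor subunits were at -0.028 (adjusted p = 0.439), serotonin, adrenergic, muscarinic and histamine receptors at -0.018 (adjusted p = 0.382), voltage-gated sodium channels at -0.10 (adjusted p = 0.0978) and schizophrenia candidate genes at 0.0024 (adjusted p = 0.807). Astrocyte markers were at -0.0062 (adjusted p = 0.321), meningeal, fibroblast and choroid plexus markers at -0.12 (adjusted p = 0.394), striatal neuron markers at 0.038 (adjusted p = 0.807), upper layer markers at -0.067 (adjusted p = 0.262) and glucocorticoid-responsive genes at -0.046 (adjusted p = 0.286). In the lesion comparison the remaining lists were deep layer markers at -0.051 (adjusted p = 0.177), glutamate receptors at -0.043 (adjusted p = 0.139), presynaptic genes at -0.025 (adjusted p = 0.289), and growth factors at -0.056 (adjusted p = 0.296). Others were heat shock genes at 0.021 (adjusted p = 0.382), microglial markers at 0.029 (adjusted p = 0.439), sterol synthesis genes at -0.0065 (adjusted p = 0.439) and dopamine signalling at 0.032 (adjusted p = 0.807). The striatal list, which shares Gnal with the dopamine list, was at 0.097 (adjusted p = 0.0528) with TTX. The schizophrenia candidates Nrg1 and Gad2 were at -0.18 ± 0.14 and 0.15 ± 0.14 after the lesion, and Nrg1 was at 0.040 ± 0.13 with clozapine and 0.16 ± 0.13 with haloperidol. The erythrocyte list was not tested because 2 of its genes were kept, Hbb at 0.26 ± 0.20 and Alas2 at 0.33 ± 0.24 with clozapine. A list's mean, median and test differed in sign for 3 lists of the lesion comparison (dopamine, schizophrenia and striatal), 3 with TTX (glutamate, postsynaptic and ribosomal), 3 with clozapine (serotonin and related receptors, sodium channels and meningeal). It did so for 6 with haloperidol (presynaptic, schizophrenia, myelin, meningeal, upper layer and heat shock) and 10 between the drugs, none of them past the threshold there.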

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

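The tests of arrays of low mean correlation, single vehicle arrays and the 3'/5' ratio on immediate early genes were chosen after seeing the results. So were those of array order in blocks and of whole runs for the lesion and TTX. For the other tests the expected outcomes were written before the tests were run. Several of these concern patterns already seen in the main results. For each comparison all arrays of its experiment were divided into the group sizes in 100 ways, the real one among them. For the neuroleptic comparisons these were all 63 arrays over 7 groups, not only those of the groups compared. The count of divisions reaching the real count is given with the real count and the highest other count in brackets. For probe sets past the threshold a chance division of single arrays could be excluded with 1 (4, 1) for haloperidol, 1 (4, 3) for medium clozapine, 2 (1, 1) for medium haloperidol, 1 (5, 1) for high haloperidol and 1 (225, 2) for clozapine against haloperidol, but not with 5 (1, 1) for high clozapine. These divisions exchange single arrays and take no account of their order in runs. With runs as a random block each of these counts was 0, but with differences of nearly the same size and larger errors, Fos at medium clozapine 2.06 ± 0.51 against 2.02 ± 0.39 and Homer1 with haloperidol 0.74 ± 0.15 against 0.73 ± 0.12. A random block widens the errors and leaves group means nearly unchanged, so the kept sizes cannot decide whether runs are the cause. The lost calls neither show nor exclude the runs as the cause. Whole runs were shuffled for these counts only in clozapine against haloperidol. For probe sets at an unadjusted p under 0.05 such a chance division could not be excluded, with 10 (1450, 2326) for the lesion, 39 (867, 2980) for TTX, 11 (1179, 2880) for their difference, 51 (711, 3103) for clozapine, 76 (507, 3167) for low clozapine, 44 (792, 3103) for low haloperidol, 58 (602, 5492) for high against low clozapine and 27 (1029, 2725) for high against low haloperidol. Other divisions with many more such probe sets than the real one, up to 5492, point to a structure of the samples. Nor could it be excluded for the number of gene lists past the threshold, with 10 (8, 10) for the lesion, 34 (3, 8) for TTX, 51 (3, 9) for clozapine, 14 (6, 11) for haloperidol, 54 (3, 9) for clozapine against haloperidol and 40 (4, 11) for the difference between lesion and TTX.

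The 225 probe sets that differed between clozapine and haloperidol may be technical in part. The 3'/5' ratio, a reading of RNA integrity, fits: 84.44% of the 225 went the way of their slope on the ratio in the lesion and TTX arrays, against 62.45% of all probe sets tested. The order of the sample numbers fits too, since 15 of 100 shuffles of the labels over whole runs gave a count as large, the highest 7037. What these numbers record is not stated in the labels. Without the 4 arrays of low mean correlation, all haloperidol, the count was 0, but with a median difference of 0.28 against 0.32 and fewer arrays, so this test cannot tell. A drug difference was not excluded, because the design gives no array free of either trend.

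Of 3 explanations tested, the 3'/5' ratio and single vehicle arrays did not account for the higher immediate early genes with either drug. Array order, the other, was tested with limits. With the 3'/5' ratio as covariate the mean log2 shift was 0.3127 with clozapine and 0.2205 with haloperidol. Exchanging whole runs of arrays between vehicle and drug gave an exact p of 0.03319 over 2380 arrangements for clozapine (real 0.32, highest other 0.47) and 0.01813 over 1820 for haloperidol (real 0.27, highest other 0.36). Both exchanges used the same 4 vehicle runs and moved runs across blocks. Within blocks clozapine minus vehicle was 0.32, 0.43 and 0.22. Haloperidol minus vehicle was 0.46 for 7 arrays, 0.20 for 1 and -0.047 for 2, so array order stays open for haloperidol. With 1 vehicle array left out the shift was at least 0.2745 and 0.2241. A response to the drugs remains possible, and handling of the vehicle rats, which both comparisons share, was not tested.

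In the direct test of the lesion effect minus the TTX effect 4 lists passed with camera's preset correlation. Of 100 divisions of the arrays, the real one among them, 40 gave at least as many lists. The difference was -0.3214 for immediate early genes, 0.03515 for respiratory chain genes, 0.03372 for ribosomal protein genes and 0.05613 for proteasome genes. For the immediate early genes the permutation p of the score difference was 0.00313, and with whole runs exchanged 0.0171. Both values hold for this list taken alone. Neither was adjusted over the gene lists tested, among which the immediate early genes stood apart most. Spread between the samples was therefore not excluded as a cause. The difference was -0.343 without the arrays of low mean correlation and -0.3267 with blocks of sample numbers, against either as the whole cause. With an estimated correlation the call was lost at adjusted p = 0.168, and those of the other 3 lists at 0.609; these 3 were also lost without the arrays of low mean correlation. The 2 experiments may differ in more than the treatment.

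Single arrays far from the others of their group were sought in 117 sets of 4 to 10 values, and 11 were found where chance gives about 1 in 20, or 5.85. Sham replicate 9 of the lesion experiment had a mean correlation with the other arrays of 0.9671 against 0.9758 to 0.9801 in the rest of its group. Haloperidol low replicate 9 had a mean correlation of 0.9618 against 0.9708 to 0.9771. Clozapine high replicate 6 had an immediate early gene score of -0.5098 against -0.1666 to 0.1068. In the same array Fos was at 8.86 against 10.12 to 11.22. Vehicle replicate 1 had Fdft1 at 13.25 against 12.96 to 13.09. Clozapine medium replicate 7 had Etv5 at 11.01 against 11.28 to 11.47. In that array Bckdk was at 11.5 against 11.81 to 12.04. Haloperidol low replicate 8 had Bckdk at 12.04 against 11.71 to 11.87. Vehicle replicate 2 had Ccn2 at 12.11 against 11.62 to 11.85. Clozapine low replicate 7 had Ccn2 at 11.43 against 11.88 to 12.12. TTX sham replicate 5 had Epb41 at 10.7 against 10.92 to 11.12.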

How the results depend on the processing

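The spline, the blocks, the runs, leaving out arrays of low mean correlation and leaving out single arrays were chosen only after the results were seen, and so were the 3'/5' ratio, the sample number and array weights for gene lists; the other alternatives were planned. Counts of probe sets kept within 1.5 times of the value reported in 127 of 168 cases and counts of lists in 19 of 30. A count of 0 that stayed 0 was taken as kept. Comparisons without a call, such as the lesion and TTX, therefore raise the 127. Of the named genes 203 values kept direction and side of the threshold, 176 kept direction only and 2 reversed. Immediate early gene shifts kept both in 134 cases, passed newly in 7, kept direction only in 10 and reversed in 3. Other lists past the threshold in the comparisons other than single dose levels kept both in 170, direction only in 71 and reversed in 1. Correlations held in 23 of 24; without the filter that of clozapine with haloperidol was 0.6778. The floor of 8 changed no call among the results it was run on, and Lrrc20, Mas1 and Naa25 had no value with the stricter filter.

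Counts of probe sets past the threshold that moved were these, and the cause was not tested. Without the filter they were 1 for the lesion, 1 for haloperidol, 3 for high haloperidol and 49 for clozapine against haloperidol. With the stricter filter they were 1 for clozapine, 7 for medium clozapine and 4 for high against low clozapine; with values as deposited clozapine had 1. In a single fit over all arrays they were 1 for the lesion, 1 for haloperidol, 6 for high against low clozapine and 391 for clozapine against haloperidol. With array weights they were 10 for medium and 2 for high clozapine, 3 for medium and 8 for high haloperidol and 531 for clozapine against haloperidol. With the 3'/5' ratio they were 1 for haloperidol, 2 for high haloperidol and 0 for clozapine against haloperidol. The sample number gave 2 for medium and 10 for high haloperidol and 4 for the difference between lesion and TTX. Its spline gave 1 for TTX, 1 for clozapine, 13 for medium clozapine and 0 for haloperidol, medium haloperidol and clozapine against haloperidol. Blocks gave 0 for the same 3, and runs as a random block 0 for these and for medium and high clozapine and high haloperidol. Without the arrays of low mean correlation they were 3 for high haloperidol, 1 for high against low clozapine and 0 for clozapine against haloperidol. Leaving out 1 array at a time gave 56 to 661 calls for clozapine against haloperidol.

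Lists past the threshold with an estimated correlation numbered 0 for the lesion, 0 for TTX, 1 for clozapine, 1 for haloperidol, 0 for clozapine against haloperidol and 0 for the difference between lesion and TTX. With probe sets averaged there were 1 for TTX and 5 for clozapine, without the filter 3 for haloperidol, and as deposited 5 for clozapine against haloperidol and 2 for the difference between lesion and TTX. The immediate early gene call was lost with an estimated correlation, which widens the spread and leaves the mean, after the lesion (-0.1821), with TTX (0.1391) and for their difference (-0.3214). Over all alternatives its adjusted p ran from 0.000551 to 0.496 for the lesion, 0.0170 to 0.578 for TTX and 1.51e-05 to 0.168 for their difference. With TTX it was also lost with probe sets averaged (0.1167), the stricter filter (0.08921), the sample number (0.1249) and its spline (0.09214). For high against low haloperidol the list reversed with the stricter filter (0.002119), array weights (0.01882) and without the arrays of low mean correlation (0.03928). Ribosomal genes reversed for the difference between lesion and TTX with values as deposited (-0.000615). In single dose levels presynaptic (-0.01978) and postsynaptic genes (-0.03058) reversed at low haloperidol with the spline, and ribosomal genes at high haloperidol without the arrays of low mean correlation (-0.008514). Hecw1 (-0.004261) and Zfp451 (0.006806) reversed between the drugs with the spline. The cause was not tested. No paired analysis was possible because replicate numbers follow the order of the samples and pair nothing. Signal over background limits the probe sets near the floor, where differences are compressed, and genes below the filter were not tested.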
